A study of Homo sapiens with 24 samples.

How the data were processed

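H3K27ac ChIP-seq and input libraries of HUVEC were made after fixation with 1% formaldehyde for 15 min, in 4 combinations of siRNA (control or PDHA1) and TNF (none or 10 ng/mL), with 3 biological replicates each. Bowtie2, HOMER and edgeR were used by the authors with the hg38 genome build, per the submitters' processing notes, and their versions and settings are not given in the sources used here. Per the file headers, the authors merged 4 per-library lists of super-enhancers, and 4 of typical enhancers, with HOMER's mergePeaks and its literal overlap setting, 1 list for each combination of siRNA and TNF. The deposited files hold start and end positions per region, with no measured signal: per the file headers and their values, the fifth of 6 columns is the constant 1, and the strand is the same throughout. The columns that named the parent libraries in the merging step were not analysed here, so no sample entered a test and none was treated as a replicate. A comparison of siRNA and TNF groups, planned in case values per library were given, was not made. Read counts were not used here, so the depth per sample is unknown and no confidence interval takes it into account. Which regions were called, and their numbers of merged intervals, may depend on depth.

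Start positions were raised by 1 so that all coordinates are 1-based. Only chromosomes 1 to 22 and X were used. The last number in each region's name was taken as the number of intervals merged into it. This was checked on the files: the position in the name equalled the midpoint of the region in all 354 super-enhancers and all 21777 typical enhancers with the number 1, and in 1 of 717 and 254 of 15824 of the others. A region with 1 interval came from 1 library, and a region with fewer than 4 was missing from at least 1 of the 4 lists. A region with 4 or more need not have been on all 4, since a library can add several intervals.

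Genes came from a table of the GRCh38.p14 assembly, the same build, which gives no strand. The design had assumed transcription start sites, a score per region and a genome sequence. Both annotated gene ends therefore took the place of the start site, regions were ranked by length, and motif density and GC content were not analysed here. A gene was linked to a region within 50 kb of either end. All 276 genes of the 15 lists matched a symbol. The lists were endothelial identity, TNF and NF-kB response, chemokines and cytokines, Notch and arteriovenous specification, TGF-beta, BMP and mesenchymal transition, the pyruvate dehydrogenase complex and pyruvate entry, glycolysis, acetyl-CoA supply and histone acetylation, markers of 6 other cell types, and housekeeping genes. The lists, the main tests and the first alternatives below, from link distance to rotation, were fixed before the data were examined.

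The super-enhancer share of each list was tested among protein-coding genes with any listed enhancer within 50 kb, and the share with any enhancer among all protein-coding genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05. Shares have exact Clopper-Pearson 95% intervals, which treat genes as independent although neighbours can share a region. Typical enhancers per gene were tested against 10000 random lists of the same size. Locations and overlaps were compared with 1000 random placements of the same lengths on the same chromosomes, from position 1 to the last gene or region of each. All p-values describe these lists and not the variation between cultures.

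Genes were named by a rule: the gene nearest to each of the 10 longest super-enhancers, up to 6 members with a super-enhancer and up to 3 without from each of the 8 endothelial, TNF, signalling and metabolic lists, PDHA1, and up to 4 members with a super-enhancer from each list of another cell type. CXCL1, CXCL2 and CXCL6 on the map, the AP-1 and HOX genes, and members of other families were named after their values were seen. Alternatives were link distances of 20 and 100 kb, the nearest gene only, all gene biotypes, the upper part of each list by length, regions over 2 kb from any gene end, no chromosome X, all protein-coding genes as background, and a rotation of the linked state along the gene order, with 10000 rotations. Added after seeing the data were a link from the gene body, random lists matched on gene length, regions with 4 or more intervals, and typical enhancers without those of 1 interval at 501 bp.

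The test of super-enhancer share was tested on simulated data built from the 18816 genes in the background. Of 200 random lists of 25 genes, Fisher's exact test called 9 and the rotation test 9, and the length-matched test called 0 of 40. With super-enhancers planted at 40% of the list, Fisher's exact test called 110 of 200 and the rotation test 90, and with 60% they called 196 and 194. A call here was an unadjusted p under 0.05, so the adjusted tests would call no more lists than these. The simulated genes were drawn at random, so the effect of neighbours that share a region was not simulated. Gene links and overlaps differed from a direct count and from bedtools in 0 cases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.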

Results

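The data collected were chromatin immunoprecipitation sequencing (ChIP-seq) libraries of human umbilical vein endothelial cells (HUVEC), primary cells of the vein wall used at passage 4. The antibody recognised histone H3 acetylated at lysine 27 (H3K27ac), a mark of active enhancers and promoters. Cells received a control siRNA or an siRNA to PDHA1, which encodes a catalytic subunit of the pyruvate dehydrogenase complex, the mitochondrial enzyme that converts pyruvate to acetyl-CoA. Each siRNA was combined with no further treatment or with tumour necrosis factor (TNF, 10 ng/mL), a cytokine that activates endothelial cells. The labels give the TNF exposure as 10 h in the treatment protocol and as 16 h in the series design. The 24 libraries formed 8 groups of 3 biological replicates, 12 libraries of H3K27ac and 12 of input chromatin. The files used here were 2 lists of regions, super-enhancers and typical enhancers, each merged over 4 H3K27ac libraries, 1 for each combination of siRNA and TNF. A super-enhancer is a stretch of neighbouring H3K27ac peaks with a high combined signal, and the remaining enhancers are called typical. No region in the lists is tied to a library, so the effects of the PDHA1 siRNA and of TNF on H3K27ac were not analysed here, and no value below has replicates. Read counts per library were not used here, so the depth behind each region is unknown.

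The lists held 1071 super-enhancers and 37601 typical enhancers on chromosomes 1 to 22 and X. Super-enhancers had a median length of 124 kb (quartiles 79.0 and 174 kb, range 10.3 to 667 kb) and covered 147 Mb, and typical enhancers had a median of 0.853 kb (quartiles 0.501 and 19.5 kb) and covered 558 Mb. The longest super-enhancer, at chromosome 14, 68439377 to 69105941 (hg38), lay nearest to ZFP36L1, which encodes a protein that binds AU-rich elements and destabilises mRNAs. Other super-enhancers among the 10 longest lay nearest to MECOM (chromosome 3, 169197959 to 169669749, 472 kb) and NFIB (chromosome 9, 14021666 to 14438234, 417 kb), which encode transcription factors, and BMP6 (chromosome 6, 7672842 to 8109913, 437 kb), a bone morphogenetic protein. CAVIN1, a coat protein of caveolae (chromosome 17, 42193858 to 42629904, 436 kb), and FLI1, an ETS transcription factor of endothelial cells (chromosome 11, 128436832 to 128860205, 423 kb), were also among them. The remaining 4 lay nearest to ATG7 (526 kb), an autophagy enzyme, the histone gene H2BC8 (517 kb), the kinase gene CDK17 (488 kb) and the splicing factor gene PRPF18 (436 kb). The nearest gene was judged from the midpoint of a region to an end of a protein-coding gene, so a region can lie mostly over another gene. Among the 10 longest this distance was greatest for MECOM (229858 bp), and it was 199388 bp for PRPF18. Each of these 10 regions was built from 6 or more merged intervals, and length grew with that number, from a median of 89.6 kb for super-enhancers with 1 interval to 164 kb for those with 4 or more.

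The number of merged intervals was used as a limited guide to how often a region was called the same way across the 4 libraries. A region with 4 or more need not have been on all 4 lists, since a library can add several intervals. Of the super-enhancers, 354 (33.1%) carried 1 interval and so came from 1 library, 209 carried 2, 165 carried 3 and 343 (32.0%) carried 4 or more. A region with fewer than 4 intervals cannot have been on all 4 lists, which applied to 728 super-enhancers (68.0%). Super-enhancers with 1 interval included those at HES1, a Notch target (chromosome 3, 194128648 to 194325459), EFNB2, the arterial ligand ephrin-B2 (chromosome 13, 106471891 to 106624045), and EP300, a histone acetyltransferase (chromosome 22, 41172397 to 41352822). Those with 4 or more included VWF, the blood clotting factor stored in endothelial granules (chromosome 12, 5974302 to 6236219, 4 intervals), and ENG, a co-receptor for TGF-beta family ligands (chromosome 9, 127698886 to 128027481, 4 intervals). Among typical enhancers, 21777 (57.9%) carried 1 interval and 9916 (26.4%) carried 4 or more, and 16064 (42.7%) carried 1 interval at the most common width of 501 bp.

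The lists were not disjoint, and 975 of the 1071 super-enhancers (91.0%) shared at least 1 bp with a typical enhancer, while 1757 typical enhancers (4.67%) overlapped a super-enhancer. The overlap covered all 728 super-enhancers with 1 to 3 intervals, among them those at VCAM1, HES1 and EP300, and 247 of the 343 with 4 or more (72.0%; two-sided Fisher's exact test, p = 1.09e-52). This contrast is largely set by how the lists are made, since enhancers of a library that are not super-enhancers are called typical. A region that was super in only some libraries would leave its peaks on the typical list of the others. The p-value says little beyond that. Among the 96 without any overlap was the region over SMAD3, a transducer of TGF-beta signals (chromosome 15, 66994147 to 67210266, 4 intervals). Typical enhancers covered on average 84.2% of the length of super-enhancers with 1 interval, against 19.5% in 1000 random placements (15.2% to 23.4%). For super-enhancers with 4 or more intervals the mean was 16.2%, below the lowest of the random placements (16.3%). When only typical enhancers with 4 or more intervals were counted, 342 super-enhancers overlapped one.

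**Figure D1:**
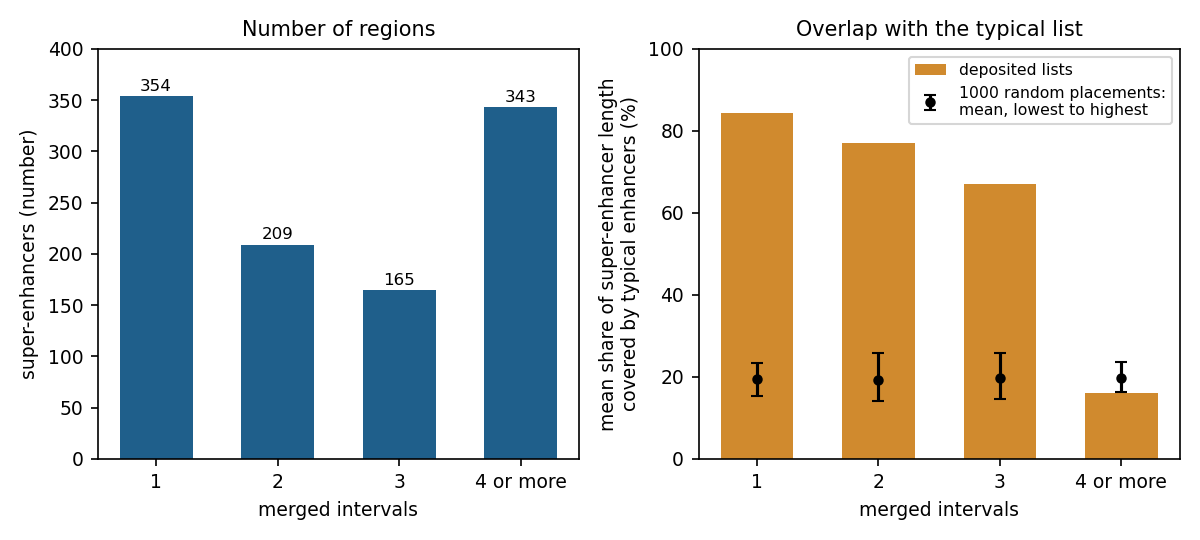
Super-enhancers by the number of merged intervals: the left bars give the number of regions, and the right bars give the mean percent of their length covered by typical enhancers. Points and error bars are the mean, lowest and highest of 1000 random placements of the same regions. The covered share was 84.2% for 1 interval, 77.0% for 2, 66.9% for 3 and 16.2% for 4 or more.

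Both kinds of region lay at genes more often than random placements did. Of the super-enhancers, 83.4% reached within 1 kb of an end of a protein-coding gene, 1.65 times the mean of 50.6% over 1000 random placements, and 91.9% overlapped such a gene, against 65.2%. Typical enhancers did so in 22.4% of cases, 1.94 times the random mean of 11.6%, and 55.7% overlapped a gene, against 46.1%. Each two-sided permutation p was 0.0020, the smallest that 1000 placements can give. Examples of super-enhancers over gene ends were those at RELA, a subunit of NF-kB (chromosome 11, 65370558 to 65672555), and CCN1, a matrix protein of growing vessels (chromosome 1, 85232994 to 85629793). The placements did not avoid assembly gaps.

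Genes that define endothelial cells carried super-enhancers far more often than other genes. Of 34 such genes, 28 (82.4%, exact Clopper-Pearson 95% interval 65.5 to 93.2%) had a super-enhancer within 50 kb of a gene end, against 21.1% of the other protein-coding genes that had any enhancer within that distance. FLI1 and ETS1, both ETS transcription factors, shared 1 region of 423 kb with 7 merged intervals. SOX17, a transcription factor of arterial endothelium, had one of 338 kb (chromosome 8, 54129039 to 54467388, 6 intervals), ENG one of 329 kb and VWF one of 262 kb. EGFL7, a secreted endothelial protein, had one of 247 kb (chromosome 9, 136481923 to 136729132, 7 intervals). KDR, the main receptor for VEGF, EMCN, a surface sialomucin, and GATA2, a transcription factor, had typical enhancers only, 3, 5 and 2 within 50 kb. A super-enhancer whose nearest gene was KDR (chromosome 4, 54904047 to 54955420, 3 intervals) lay beyond that distance. The odds ratio was 17.5 (95% interval 7.09 to 51.6) and the adjusted p was 6.52e-13 (Fisher's exact test, two-sided, Benjamini-Hochberg over 15 lists). With super-enhancers and typical enhancers of 4 or more intervals, 15 of 28 genes (53.6%, adjusted p = 2.12e-07) had a super-enhancer, against 10.2% of other genes. Leaving out regions within 2 kb of a gene end kept 172 super-enhancers (16.1%) and no list passed, but only 1.05% of other genes then had one and 0.209 of the 20 endothelial identity genes were expected to (0 observed, adjusted p = 1), so that setting is not informative for lists of this size.

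**Figure D2:**
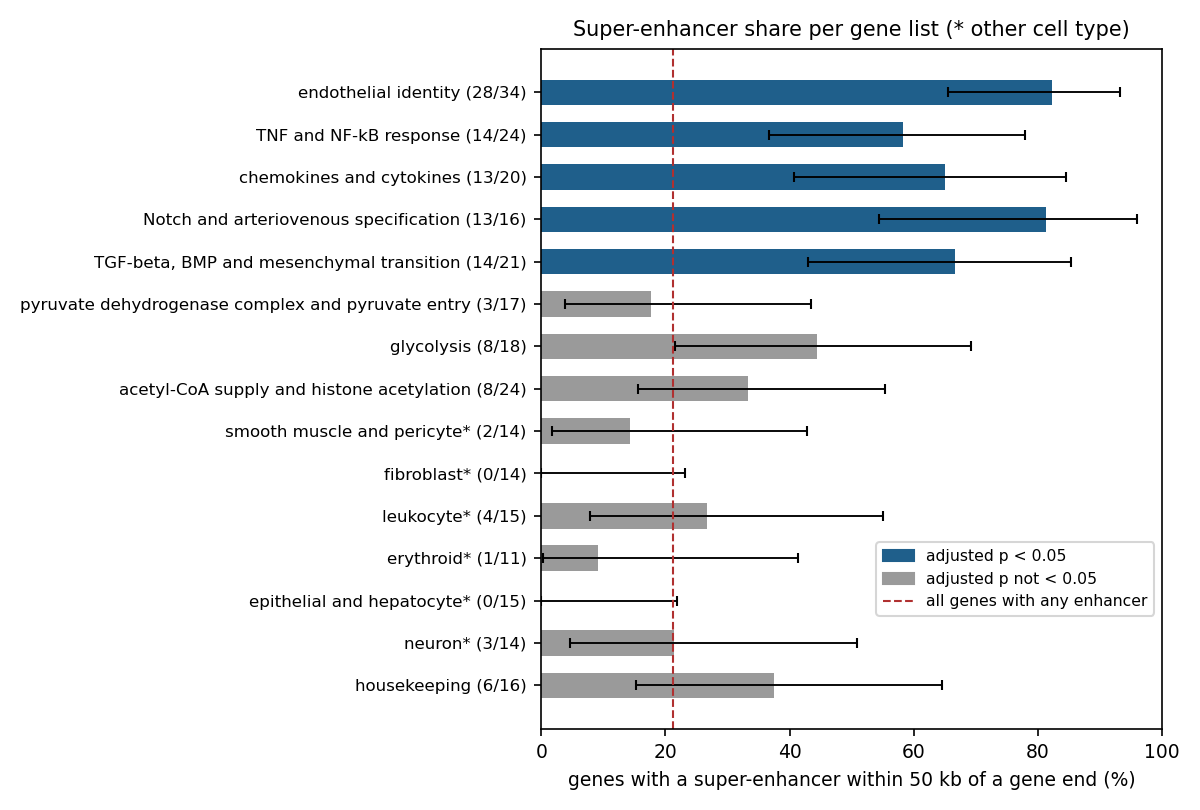
Percent of the genes in each list that had a super-enhancer within 50 kb of a gene end, among genes with any enhancer within that distance (numbers in brackets: genes with one, genes in the list). Error bars are exact 95% binomial intervals and the dashed line is the share among all such genes (21.2%). The 5 blue lists, from endothelial identity (82.4%) to TNF and NF-kB response (58.3%), passed the adjusted Fisher's exact test.

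Genes of the TNF response also lay near super-enhancers more often than other genes. In the list of TNF and NF-kB response genes, 14 of 24 (58.3%, interval 36.6 to 77.9%) had one, against 21.1% of other genes (odds ratio 5.22, adjusted p = 2.40e-04, Fisher's exact test). VCAM1, the adhesion molecule that binds leukocyte integrins, was partly overlapped by one of 154 kb (chromosome 1, 100584172 to 100737844, 2 intervals). IRF1, an interferon-regulated transcription factor (chromosome 5, 132369695 to 132521050, 3 intervals), and TNFRSF1B, a TNF receptor (chromosome 1, 12119541 to 12255469, 2 intervals), had shorter ones of 151 and 136 kb. The longest within 50 kb of genes of the list were at IER3, an early stress response gene (chromosome 6, 30485624 to 30830872, 345 kb, 9 intervals), RELA (302 kb) and RIPK1, a kinase of the TNF receptor complex (chromosome 6, 2764105 to 3025729, 262 kb, 5 intervals, 38238 bp from the gene). ICAM1, a second leukocyte adhesion molecule, F3, the initiator of clotting known as tissue factor, and CD40 had 1, 3 and 2 typical enhancers and no super-enhancer within 50 kb. The call was lost when only the longer regions of each list were used, split at the median length (7 of 24 genes, 29.2%, against 14.6% of other genes, adjusted p = 0.220). It was also lost with regions of 4 or more intervals (4 of 20, 20%, against 10.3%, adjusted p = 0.534).

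Chemokine and cytokine genes had a super-enhancer in 13 of 20 cases (65%, interval 40.8 to 84.6%, odds ratio 6.92, adjusted p = 1.09e-04, Fisher's exact test), through 10 regions. IL6, an inflammatory cytokine, lay at one of 170 kb (chromosome 7, 22560075 to 22730394, 4 intervals). CXCL8, a neutrophil attractant, lay under one of 125 kb (chromosome 4, 73654087 to 73778888, 3 intervals). IL32, a cytokine (chromosome 16, 3020356 to 3160172, 140 kb), CX3CL1, the membrane-bound chemokine fractalkine (chromosome 16, 57237827 to 57339781, 102 kb), CSF3, a granulocyte growth factor (chromosome 17, 40053951 to 40141391, 87.4 kb), and IL1A (chromosome 2, 112760721 to 112837635, 76.9 kb) had 3, 2, 2 and 1 intervals. The regions of CX3CL1 and CSF3 lay 32709 and 36138 bp from the genes. CCL20, CCL5 and CXCL10, which attract lymphocytes, had 2, 1 and 1 typical enhancers and no super-enhancer. The call was lost with the longer regions of each list (3 of 20, 15%, against 14.6% of other genes, adjusted p = 1) and with regions of 4 or more intervals (3 of 16, 18.8%, against 10.3%, adjusted p = 0.585).

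**Figure D3:**
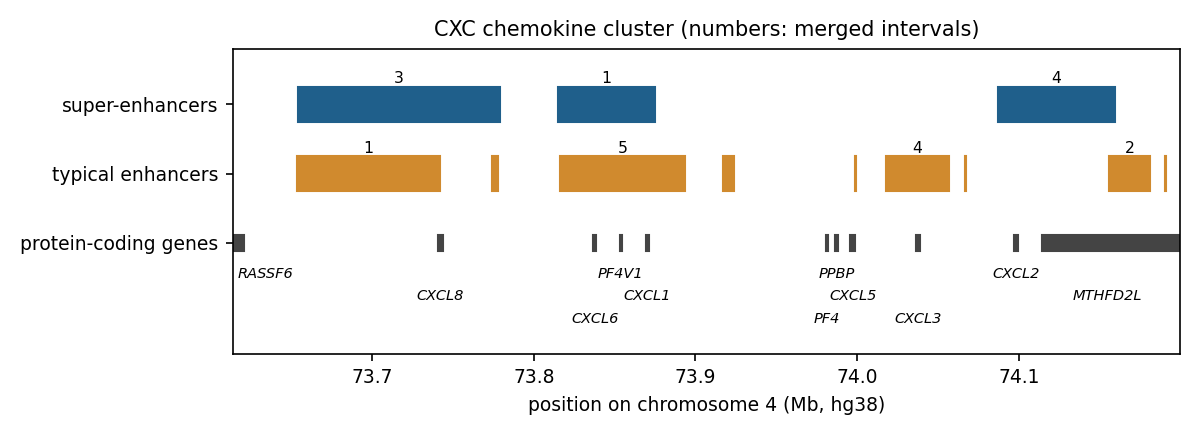
Map of the CXC chemokine cluster on chromosome 4 (horizontal axis: position in Mb, hg38) with super-enhancers, typical enhancers and protein-coding genes drawn to scale. Numbers above the longer regions give their merged intervals. The super-enhancers over CXCL8 (3 intervals), CXCL6 and CXCL1 (1 interval) and CXCL2 (4 intervals) each overlap at least 1 typical enhancer.

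Notch and arteriovenous genes, which set arterial and venous fate, had a super-enhancer in 13 of 16 cases (81.3%, interval 54.4 to 95.9%, odds ratio 16.2, adjusted p = 3.74e-06, Fisher's exact test). NOTCH1, a Notch receptor, shared the 247 kb region of EGFL7. JAG1, a Notch ligand (chromosome 20, 10461748 to 10675475, 214 kb), HES1 (197 kb) and EFNB2 (152 kb) had regions of 3, 1 and 1 intervals. DLL4, the ligand of arterial and tip cells (chromosome 15, 40893846 to 41043766, 150 kb), and NOTCH4, an endothelial Notch receptor (chromosome 6, 32108444 to 32256569, 148 kb), had regions of 2 intervals. GJA5, an arterial connexin, and HEY1, a Notch target, had 1 and 2 typical enhancers only, and CXCR4, a chemokine receptor, had no listed enhancer within 50 kb. With regions of 4 or more intervals 2 of 9 genes had a super-enhancer, 22.2% against 10.3% of other genes, and the call was lost (adjusted p = 0.585).

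Genes of TGF-beta and BMP signalling and of mesenchymal transition had a super-enhancer in 14 of 21 cases (66.7%, interval 43.0 to 85.4%, odds ratio 7.46, adjusted p = 4.55e-05, Fisher's exact test). CCN1 had the longest, at 397 kb with 7 intervals. ACVRL1, an endothelial receptor for BMP9 (chromosome 12, 51809329 to 52070888, 262 kb), TGFB1, the ligand itself (chromosome 19, 41261509 to 41502707, 241 kb), and SMAD3 (216 kb) each had 4 intervals. SMAD6, an inhibitor of BMP signals (chromosome 15, 66577864 to 66804203, 226 kb), had 5, and SNAI1, a repressor active in mesenchymal transition (chromosome 20, 49979772 to 50193323, 214 kb), had 4. BMPR2, a BMP receptor, ID2, a BMP target, and SNAI2 each had 3 typical enhancers and no super-enhancer. The call held with regions of 4 or more intervals (9 of 17 genes, 52.9%, against 10.2% of other genes, adjusted p = 1.04e-04).

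PDHA1, the siRNA target, had no super-enhancer and 2 typical enhancers within 50 kb. In the list of the pyruvate dehydrogenase complex and pyruvate entry, 3 of 17 genes (17.6%, interval 3.80 to 43.4%) had a super-enhancer, against 21.2% of other genes (odds ratio 0.797, 0.147 to 2.86, adjusted p = 1, Fisher's exact test). These were DLD and DLAT, other subunits of the complex (chromosome 7, 107879351 to 108115441, 4 intervals, and chromosome 11, 111922955 to 111978585, 1 interval), and PDP1, the phosphatase that activates it (chromosome 8, 93846561 to 93960461, 1 interval). The DLAT region lay 46823 bp from the gene. LDHA and LDHB, the subunits of lactate dehydrogenase, and MPC1, a subunit of the mitochondrial pyruvate carrier, had 2, 3 and 3 typical enhancers only.

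Glycolysis genes had a super-enhancer in 8 of 18 cases (44.4%, interval 21.5 to 69.2%, odds ratio 2.98, 1.02 to 8.39), which did not pass the test (Fisher's exact p = 0.0365, adjusted p = 0.0913). They included PGAM1, a mutase (chromosome 10, 97318459 to 97597766, 279 kb), GPI, an isomerase (chromosome 19, 34171628 to 34366394, 195 kb), and PFKP, the platelet-type phosphofructokinase (chromosome 10, 3045366 to 3197810, 152 kb). TPI1 and ENO2 shared 1 region (chromosome 12, 6818878 to 6971794, 153 kb), and GAPDH had one of 145 kb (chromosome 12, 6423687 to 6568966). ALDOC, ENO1 and HK1 had 1, 2 and 4 typical enhancers only. The list passed in 5 of 13 alternative settings, such as a link distance of 20 kb (adjusted p = 0.0287). It did not pass with the nearest gene only (2 of 12, adjusted p = 0.568), and with regions of 4 or more intervals its share lay below that of other genes (1 of 14, 7.14%, against 10.3%, adjusted p = 1). Genes of acetyl-CoA supply and histone acetylation had a super-enhancer in 8 of 24 cases (33.3%, interval 15.6 to 55.3%, adjusted p = 0.310), with regions at the deacetylase genes HDAC1, HDAC2, HDAC3 and HDAC7 of 141, 143, 157 and 144 kb and at EP300 of 180 kb. The HDAC1 and EP300 regions overlapped only a part of these genes at an end, and another gene was nearest to the HDAC1 region. KAT5, an acetyltransferase, lay 39463 bp from the RELA region. ACSS1 and ACSS2, which make acetyl-CoA from acetate, had 3 typical enhancers each, and BRD2, a reader of acetylated histones, had 1. The list passed only with a link distance of 100 kb (adjusted p = 0.0248) among the 13 settings, and with regions of 4 or more intervals its share was 10% (2 of 20), against 10.3% of other genes (adjusted p = 1).

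None of the 6 lists of other cell types passed the test in either direction. A lower share could not have been called in lists this small. Even with 0 genes linked, the fibroblast and the epithelial and hepatocyte lists gave unadjusted Fisher's exact p of 0.0515 and 0.0525. Fibroblast genes (0 of 14, upper limit 23.2%) and epithelial and hepatocyte genes (0 of 15, upper limit 21.8%) had no super-enhancer within 50 kb, with an adjusted p of 0.0985 each (Fisher's exact test). Smooth muscle and pericyte genes had one in 2 of 14 cases (SMTN and RGS5, adjusted p = 0.863), leukocyte genes in 4 of 15 (SPI1, PTPRC, CD3D and CD3E, adjusted p = 0.673), erythroid genes in 1 of 11 (KLF1, adjusted p = 0.650) and neuronal genes in 3 of 14 (SLC17A7, GRIN1 and SYT1, adjusted p = 1). The region reached a gene end only at SPI1, a transcription factor of blood cells (chromosome 11, 47374032 to 47642590), and lay between 1318 bp (RGS5) and 45557 bp (KLF1) from the ends of the others. The RGS5 region lay inside that gene, and the regions of the remaining genes lay outside them. Housekeeping genes had a super-enhancer in 6 of 16 cases (37.5%, adjusted p = 0.208). With regions of 4 or more intervals it was 5 of 15 (33.3%, against 10.2% of other genes, Fisher's exact test, adjusted p = 0.0704). That share lay above those of the TNF, chemokine and Notch lists in the same setting, and below those of the endothelial identity and TGF-beta lists.

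Having any enhancer did not separate the lists, since 18816 of 19974 protein-coding genes (94.2%) had one within 50 kb. All members of 12 lists had one, among them endothelial identity (34 of 34) and fibroblast (14 of 14), and the shares of the Notch, erythroid and epithelial lists were 94.1%, 91.7% and 93.8%. By Fisher's exact test 0 of 15 lists passed, 0 had an unadjusted p under 0.05, and the rotation and length-matched tests also called 0. Fisher's exact test could not have called a higher share, since the largest list, endothelial identity, gave p = 0.263 with all 34 genes linked. Only a lower share could have been called. Genes had a mean of 2.15 typical enhancers within 50 kb. The pyruvate dehydrogenase list had 2.82 ± 1.33 (SD over 17 genes, permutation p = 0.0452, adjusted p = 0.359) and the acetyl-CoA and histone acetylation list 2.71 ± 1.27 (24 genes, permutation p = 0.0478, adjusted p = 0.359). These 2 lists had an unadjusted p under 0.05 in the permutation test, and 0 of 15 passed after adjustment.

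The share of super-enhancers with 4 or more intervals was compared between lists. It was 60% near TGF-beta, BMP and mesenchymal genes (9 of 15 regions, such as CCN1 and SMAD3), 48.3% near endothelial identity genes (14 of 29, such as SOX17 and VWF) and 83.3% near housekeeping genes (5 of 6). It was 30.8% near TNF and NF-kB genes (4 of 13), 20% near chemokines and cytokines (2 of 10) and 15.4% near Notch genes (2 of 13). Of 13 lists with at least 1 super-enhancer, 0 differed from the remaining super-enhancers after adjustment (Fisher's exact test, lowest adjusted p = 0.168), and the TGF-beta and housekeeping lists had unadjusted p of 0.0258 and 0.0146. The erythroid, smooth muscle, pyruvate dehydrogenase, leukocyte and neuronal lists had only 1, 2, 3, 3 and 3 super-enhancers. The lack of a call says little of lists with so few.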

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

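The settings with 4 or more intervals, the gene body, length-matched lists, typical enhancers without those of 1 interval at 501 bp, and every alternative for the share of super-enhancers with 4 or more intervals, were chosen after the data were examined. Of the 5 lists that passed for super-enhancer share, 0 passed with regions over 2 kb from any gene end and 2 passed with regions of 4 or more intervals. The first setting leaves 172 of 1071 super-enhancers and 1.04% of other genes near one, so it says little of lists this small: the endothelial, TNF, chemokine and Notch lists had 0 linked genes where at most 0.209 were expected (adjusted p of 1 each), and TGF-beta had 7.69% (1 of 13, adjusted p 0.638). The second gave 0.534 for TNF (20%), 0.585 for chemokines (18.8%) and 0.585 for Notch (22.2%), against 10.3% of other genes in each, and the cause was not tested. With the upper part of each list by length, the TNF list had 0.220 and the chemokine list 1; that setting removes the shorter regions of these lists and gives median lengths of 174 and 19.5 kb. Overlap with the typical list fell from 975 to 342 super-enhancers when only typical enhancers with 4 or more intervals counted, which removes most of that list. The other 117 main values under an alternative kept their call or stayed near their count, among them the rotation test (adjusted p 0.00075 for endothelial, TNF, Notch and TGF-beta and 0.0204 for chemokines). Among secondary values 722 stayed, 52 moved and 6 newly passed, including glycolysis (0.0287 at 20 kb, 0.158 by rotation, 1 with regions of 4 or more intervals). Of the 55 named listed genes with a super-enhancer, 46 had one within 20 kb and 23 had one with 4 or more intervals. No paired analysis was possible because the lists are merged over libraries and carry no replicate; leaving out a replicate and the fits per library were not run for the same reason, and the motif settings were not run without a genome sequence. The depth per library is unknown, so what it limits was not assessed.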

Other observations

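The gene family comparisons, the placement test outside the windows around recurrent enhancers, and the removal of non-member symbols from the families, made once family results had been seen, were chosen after the data were examined. Families were taken from gene symbols, and 17 were tested like the gene lists. By Fisher's exact test 8 differed from other genes in super-enhancer share, and 3 did so by the rotation test, which keeps neighbouring genes together. HOX genes, which pattern the body axis, had a super-enhancer in 29 of 37 cases (78.4%, rotation adjusted p = 0.0068), through 3 regions: all 11 HOXA genes (chromosome 7, 27095856 to 27190219, 4 intervals), 9 of 10 HOXB genes (chromosome 17, 48541029 to 48636472, 4 intervals) and all 9 HOXD genes (chromosome 2, 176122924 to 176189797, 1 interval). None of the 9 HOXC genes had one. Olfactory receptor genes had one in 10 of 293 cases (3.41%, rotation adjusted p = 0.0034) and any enhancer in 293 of 392 (74.7%, rotation adjusted p = 0.0034). Zinc finger genes with ZNF symbols had a super-enhancer less often than other genes (62 of 511, 12.1%, rotation adjusted p = 0.0181) and any enhancer more often (511 of 517, 98.8%, rotation adjusted p = 0.0068).

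AP-1 factors, which act with NF-kB in inflammatory gene control, had a super-enhancer in 7 of 11 cases (63.6%, Fisher's exact adjusted p = 0.0119), which did not pass by rotation (adjusted p = 0.0558). They were JUN (chromosome 1, 58654301 to 58911649, 5 intervals), FOS (chromosome 14, 75123361 to 75296477, 1 interval), JUNB, JUND, FOSB, FOSL1 and FOSL2. Ribosomal protein genes had one in 26 of 77 cases (33.8%, adjusted p = 0.0377, rotation 0.0558), integrins in 11 of 26 (42.3%, 0.0405, rotation 0.120), FOX factors in 3 of 43 (6.98%, 0.0490, rotation 0.0776) and keratins in 4 of 49 (8.16%, 0.0490, rotation 0.568). The other 9 families had adjusted p from 0.0689 (collagen IV and laminins, 8 of 18) to 0.780 (ADAMTS proteases, 3 of 19), with respiratory chain and ATP synthase genes at 14 of 81 (17.3%, adjusted p = 0.526).

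Typical enhancers from 1 library at the most common width made up 16064 of 37601, and 11.8% of them lay within 10 kb of a protein-coding gene end, 0.696 times the mean of random placements (17.0%), against 63.9% of typical enhancers with 4 or more intervals. Outside the windows of 10 kb around recurrent enhancers, which hold many gene ends, the share was 11.6% against 11.8% in random placements (10.8% to 12.7%), a ratio of 0.985. The first share lay below every placement (lowest 16.1%), a shortage near gene ends that scatter alone does not give, and only the second ratio is consistent with background calls scattered without regard to genes. Only 1.79% lay within 10 kb of a recurrent enhancer (typical or super, with 4 or more merged intervals), 0.0808 times the random mean (22.2%). This ratio lay below the bound of 1.2 set beforehand for a weak fringe of enhancer neighbourhoods. Peaks that close may have been joined to the larger region before listing, which was not measured. The test therefore does not decide whether these regions are such a fringe. No biological explanation was tested, since no region is tied to a group.

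A candidate explanation for the overlap of the lists is that regions near the limit between the classes were super-enhancers in some libraries and typical in others. All 728 super-enhancers with 1 to 3 intervals (100%) overlapped a typical enhancer, against 72.0% of the others, and for each of these 728 the intervals of the super-enhancer and of the typical enhancers it overlapped came to 4 or more. Such overlap is largely set by how the lists are made, because a region that was super in only some libraries leaves its peaks on the typical list of the others. The interval totals do not show that all libraries took part, since a library can add several intervals. Neither value therefore tests whether the regions lay near the limit. The overlap of 91.0% lay 11.0 percentage points above the mean of random placements (80.0%) and above their highest value (83.4%). The placements did not keep regions near genes, where both lists lay more often than random placements did. This excess by itself therefore cannot decide whether chance overlap of long regions is the whole cause. The excess came from super-enhancers with 1 to 3 intervals (random mean 77.3%, highest 81.6%), while those with 4 or more lay below every placement (mean 85.7%, lowest 79.0%). Typical enhancers covered on average 78.2% of the length of super-enhancers with 1 to 3 intervals, against at most 22.6% in random placements. That gap argues against chance overlap as the whole cause for these 728 super-enhancers. For those with 4 or more intervals the covered share was 16.2%, below the lowest placement (16.3%). A change of class with TNF or the PDHA1 siRNA stays open and untested.

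Of the 23 super-enhancers near the TNF and chemokine genes, all but 6 carried fewer than 4 intervals. Those were therefore not called as super-enhancers in at least 1 of the 4 libraries, of which 2 had TNF. Which libraries lacked them is unknown. Near the TNF and chemokine lists 6 of 23 (26.1%) carried 4 or more intervals, against 14 of 29 (48.3%) near endothelial identity genes (odds ratio 0.385, 95% interval 0.0953 to 1.41, Fisher's exact p = 0.152), so a difference cannot be told apart from none with so few regions. Super-enhancers of matched length had 27.8% (95% range 13.0 to 43.5%), from which the TNF and chemokine regions differed by -1.69 percentage points, but merging more intervals itself lengthens a region, so this match does not decide whether length is the explanation.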
